A study of Dictyostelium discoideum with 123 samples.

How the data were processed

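Single cells of Dictyostelium discoideum, a soil amoeba that aggregates when starved and sorts into prespore and prestalk cells, were profiled after 14 h of development, at the mound stage. The strain was AX3 carrying a red fluorescent histone in the rps30 locus, per the labels. Mounds were broken up with EDTA and a needle, and cells were captured on Fluidigm C1 chips, on which chambers with no cell or with several cells were identified by microscopy, per the labels' protocols. cDNA was made with the SMARTer kit and libraries with Nextera XT, with ERCC spike-in RNA (92 transcripts) in each chamber, per the labels. These kits add no molecular identifiers, so a count is a count of reads, and intervals cover counting error only.

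The authors deposited raw read counts per gene for 123 cells, in 1 table of all cells and in 1 table per replicate, and the values of the 2 kinds of table were identical. The tools named in the submitters' processing notes are TopHat2 2.0.9, HTSeq and Picard 1.119, with no role given for each. The genome build, the annotation and whether counting used strand are not given in the sources used here. The authors excluded 7 cells for few reads, many mitochondrial reads or a missing contiguous part of the transcriptome, per the labels of the series, and these were left out, which left 116 cells: 29, 44 and 43 in experimental replicates 1, 2 and 3. Each cell is 1 library and not a replicate, so n is the number of experimental replicates, 3. The sample titles follow 1 naming scheme in replicates 1 and 2 and another in replicate 3, and the labels do not say what it marks. The rows for reads on no feature and on more than 1 feature stayed out of library sizes and tests. Their medians per replicate were 3.18%, 2.93% and 2.20% of the gene reads for no feature, and 3.20%, 4.14% and 2.52% for more than 1 feature. The other 3 summary rows were 0 in every cell.

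Of 14025 gene rows, 13220 matched a locus tag of the assembly dicty_2.7 (strain AX4), which was used for names and for the order of genes, and 805 did not. No positions are given, because the build behind the counts is not named. Counts of genes with near-identical copies, of overlapping genes and of antisense partners are uncertain, since reads could be split or dropped between them. This covers symbols ending in -1 or -2, which mark copies of a duplicated part of chromosome 2.

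Counts were scaled to CPM over the gene reads of each cell, spike-ins apart. Cells were grouped without reference to replicate by Ward clustering into 3 clusters on the z-scores of log2(CPM + 10) of 22 marker genes with a mean of at least 10 CPM, 10 prespore and 12 prestalk (Python 3.11.15, SciPy 1.17.1, scikit-learn 1.9.0). The cluster with the highest prespore score was called prespore-like and the one with the highest prestalk score prestalk-like; the remaining cluster was left unnamed and is called the third cluster. Doublets were not called by software; the authors identified multiple captures by microscopy, per the labels. Counts were summed per replicate and class. The third cluster of replicate 3 held 2 cells, fewer than the minimum of 3, so 8 sums were tested and comparisons with the third cluster rest on replicates 1 and 2.

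The sums were compared with the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3), with TMM scaling, filterByExpr, the replicate as a block and Benjamini-Hochberg adjustment at 0.05. Marker genes that made the classes stayed out of the tests. The classes come from the same cells' expression, so p-values state how alike the sums were across replicates, not that classes exist. The standard error of a log2 fold change was taken from its F statistic. Of 18 gene lists, 17 had at least 3 tested members and were tested with camera of limma 3.58.1 at a preset correlation of 0.01; camera with an estimated correlation and fry stand beside it. Exact sign-flip permutation tests over 3 replicates cannot go below a two-sided p of 0.25.

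Markers, lists, tests, most alternatives and the rule for named genes were fixed before the data were examined. Among genes past the threshold with the same direction in every replicate and a mean of at least 50 CPM, the rule takes the 10 largest log2 fold changes with a symbol in each direction and up to 3 without a symbol. It adds up to 4 members per list by adjusted p, with no minimum mean, of which the text names those past the threshold. For variability without classes, the 10 genes with a symbol and the highest median ratio outside the markers were named. A fold against a class without any read was computed against a floor of 3 reads over that class. Such a fold is not a lower bound, since counts are of reads and not of molecules.

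The steps were tested on simulated data drawn from the real sums, with 200 genes changed. At the spread of the real sums, the prespore-like versus prestalk-like simulation recovered 0% of 2-fold and 4-fold changes, 4% of 8-fold and 24% of 16-fold changes among 11229 genes, and 6.67% of its calls were false. For the third cluster against prespore-like cells, 0%, 2%, 14% and 32% were recovered among 11232 genes, with 14.3% of calls false. For the third cluster against prestalk-like cells, 0%, 0%, 6% and 26% were recovered among 11229 genes, with 0% false. With the dispersion divided by 20, the prespore-like versus prestalk-like simulation recovered 48%, 96%, 100% and 100% of the same sizes among 11234 genes, with 10.4% of calls false. For the third cluster, 46%, 100%, 100% and 100% were recovered against prespore-like cells among 11199 genes, with 8.47% false, and 42%, 88%, 100% and 100% against prestalk-like cells among 11192 genes, with 5.17% false. The common dispersion of the real sums was 0.999, with 3 residual degrees of freedom. At the spread of the real sums, the simulation thus missed most changes of up to 16-fold. Its changed genes were drawn from low and high levels alike, so it does not give the recovery of abundant genes. Smaller changes passed in the real sums, such as ctxB at 3.06-fold between prespore-like and prestalk-like cells. In a simulation of the list test, the 1 list moved 2-fold was found, and 0 of the others. Its genes were drawn independently, so it cannot show false list calls that arise where genes vary together. In a simulation of the variability ranking, 132 genes stood in the top in every replicate, and 132 of them were among the 200 made more variable.

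Alternatives were DESeq2 1.42.0, other scalings including spike-in totals, no filter, no replicate block, each replicate left out, all 123 cells, thinning each cell to 700000 reads (0 kept cells were shallower), another pseudocount of 1, centring of markers within replicates, 2 or 4 clusters, tertiles of the difference of scores, and clusters from 500 other genes.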

Results

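The data are read counts of 116 single cells from Dictyostelium mounds, taken 14 h after the start of development, in 3 experimental replicates of 29, 44 and 43 cells. A kept cell had between 731938 and 5537133 gene reads. Median gene reads per cell were 3542060 in replicate 1, 3300590 in replicate 2 and 1638950 in replicate 3, and median numbers of genes detected were 7143, 6177 and 4460. Spike-in RNA took a median of 24.5%, 20.3% and 36.95% of gene and spike-in reads. All cells belong to 1 group, the mound, and the series title speaks of a stochastic choice of fate. The comparisons ask how cells that express prespore genes, cells that express prestalk genes and the remaining cells differ.

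The spore coat gene cotB was abundant in 1 set of cells and low elsewhere, with 3834 ± 1173 CPM in prespore-like cells, 20.4 ± 11.1 CPM in prestalk-like cells and 15.1 ± 13.04 CPM in the third cluster (mean ± SD of replicate means, n = 3). The spore coat gene cotE, too low to enter the clustering, had 11.4 ± 4.82, 6.26 ± 10.8 and 0.543 ± 0.518 CPM in the same order. The prespore gene pspA had 5548 ± 1752, 132 ± 121 and 21.9 ± 21.9 CPM. The gene of a stalk matrix protein, ecmA, had 149 ± 69.4 CPM in prespore-like cells, 5693 ± 731 CPM in prestalk-like cells and 29.4 ± 18.5 CPM in the third cluster, and ecmB had 187 ± 114, 2395 ± 2281 and 7.54 ± 10.7 CPM. These markers defined the classes, so their levels describe the classes and are not a finding. The panels held genes that did not part the classes in this way, such as pspC with 15.2 ± 11.2, 1.26 ± 1.07 and 18.6 ± 4.89 CPM, and mybE with 585 ± 223, 546 ± 128 and 100.2 ± 95.2 CPM. Among the 10 genes that led each class by fold, 7 were prespore markers in prespore-like cells and 1, ecmA, was a prestalk marker in prestalk-like cells. None of the 10 that led the third cluster was a marker; DDB_G0272200, DDB_G0267282 and rae1 were among them.

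**Figure D1:**
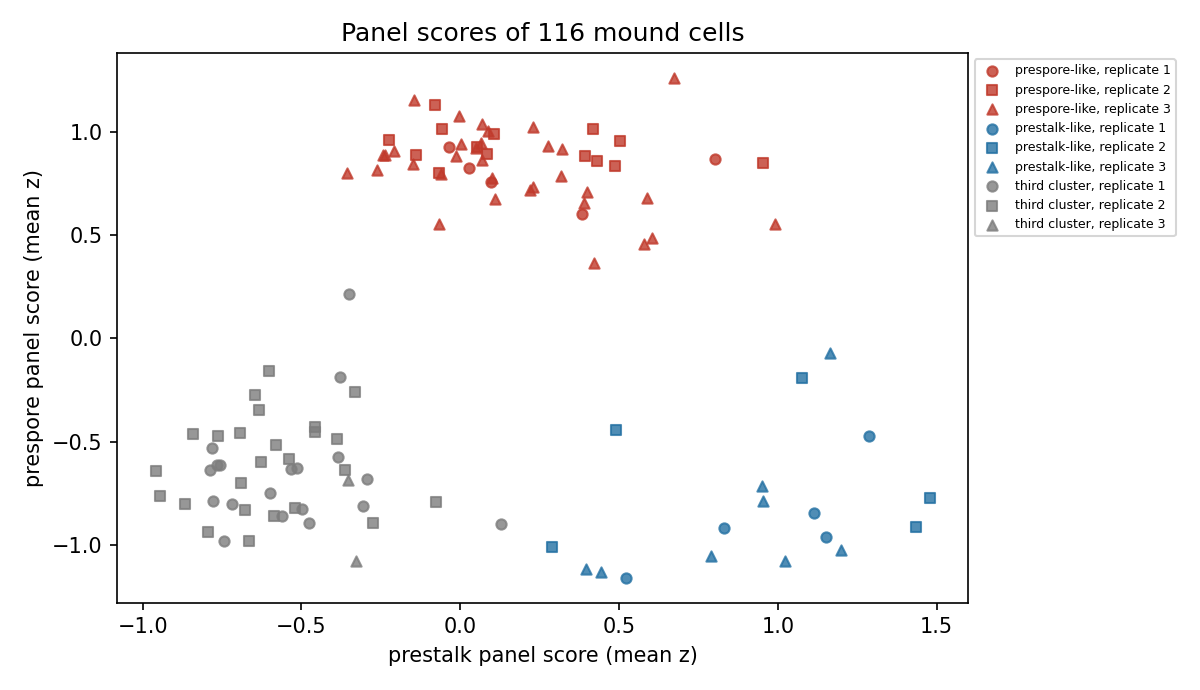
Each point is 1 of the 116 kept cells, with the mean z-score of 12 prestalk genes on the x axis and of 10 prespore genes on the y axis. Colour gives the class and shape the replicate. Both scores are above 0 in 35 cells, all of them prespore-like, and in 0 of the 46 cells of the third cluster.

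Prespore-like cells made up 17.2% of replicate 1 (5 of 29 cells, exact 95% interval 5.85 to 35.8%), 31.8% of replicate 2 (14 of 44, 18.6 to 47.6%) and 76.7% of replicate 3 (33 of 43, 61.4 to 88.2%). Their mean share was 41.9% ± 31.01 (SD, n = 3). Prestalk-like cells made up 17.2% (5 of 29, 5.85 to 35.8%), 11.4% (5 of 44, 3.79 to 24.6%) and 18.6% (8 of 43, 8.39 to 33.4%), with a mean of 15.7% ± 3.85 (SD, n = 3). The third cluster held 65.5% (19 of 29, 45.7 to 82.1%), 56.8% (25 of 44, 41.03 to 71.7%) and 4.65% (2 of 43, 0.568 to 15.8%), with a mean of 42.3% ± 32.9 (SD, n = 3). Replicate 3 also had the lowest depth, and 0 cells changed class when every cell was thinned to 700000 reads and clustered again. With 4 clusters, 46 of the 52 prespore-like cells fell in an unnamed cluster, and the name went to 6 cells of replicate 3, so the mean share of 4.65% is that of another set of cells.

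**Figure D2:**
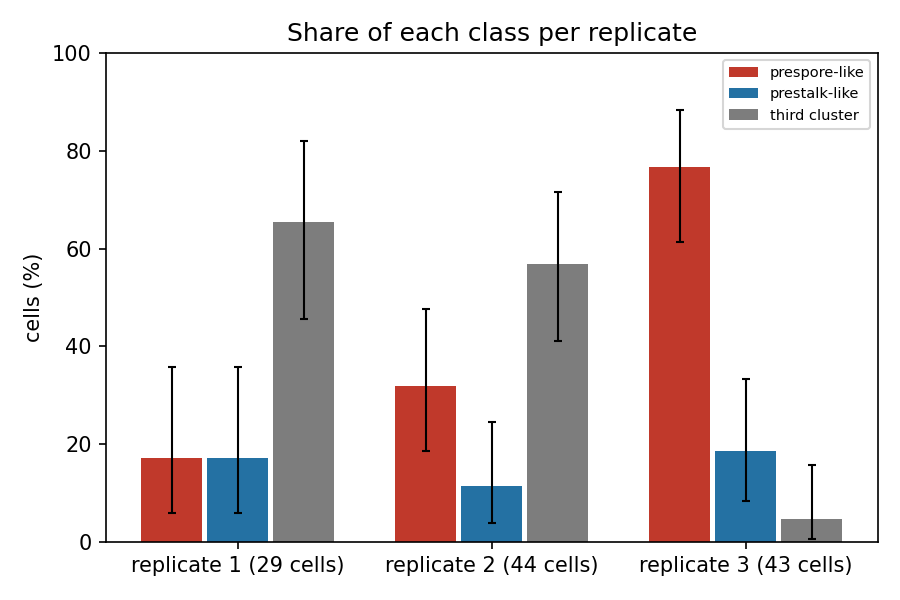
Bars give the percent of cells in each class per replicate, and error bars the exact 95% binomial interval. Prespore-like cells take 17.2% and 31.8% of replicates 1 and 2 and 76.7% of replicate 3, where the third cluster holds 4.65%.

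Genes outside the markers parted the cells in the same way. Ward clusters on the 500 most variable other genes had an adjusted Rand index of 1 with the marker clusters, and k-means on either set of genes had 1 as well. After the values of each gene were shuffled over cells the index was 0.00769. It was 0.550 with 100, 200 and 250 genes, 1 with 300, 1000 and 2000 genes, and 0.969 with 5000. With 200 genes, prespore-like and prestalk-like cells fell together and the third cluster divided into 26 and 20 cells. With log2(CPM + 1) the index was 0.521. Within single replicates it was 0.626, 0.436 and 1.

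Prespore genes varied together across cells in each replicate, and so did prestalk genes, though weakly in replicate 3. The median Spearman rho over pairs of prespore genes was 0.612 ± 0.160 (mean ± SD, n = 3 replicates), over pairs of prestalk genes 0.319 ± 0.157, and between the panels 0.0219 ± 0.189. In replicates 1, 2 and 3 it was 0.428, 0.721 and 0.687 for prespore genes and 0.457, 0.351 and 0.149 for prestalk genes. Between the panels it was 0.0787, 0.176 and -0.189 in the same order. Both within-panel values lay above the between-panel value in 3 of 3 replicates, by 0.590 ± 0.266 for prespore and 0.297 ± 0.107 for prestalk genes. The exact two-sided sign-flip permutation p was 0.25 for each, the smallest that 3 replicates allow. Without replicate 1 the mean between panels was -0.00646, and without replicate 2 it was -0.0550.

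Prespore-like and prestalk-like cells differed in 155 of 11541 genes, 76 higher in prespore-like and 79 higher in prestalk-like cells. Higher in prespore-like cells were psvA at 1458 ± 434 against 27.4 ± 21.8 CPM (mean ± SD of 3 sums each, adjusted p = 0.0225), colC, which encodes a colossin, at 2468 ± 731 against 42.3 ± 55.8 CPM (adjusted p = 0.0450), pgtD at 384 ± 143 against 5.73 ± 7.73 CPM and cbpI at 221 ± 88.4 against 5.82 ± 6.90 CPM. The aquaporin gene aqpA had 27407 reads against 0 in the prestalk-like sums, 2745-fold higher against the floor. The catalase gene catB had 36451 reads against 1, the tripeptidyl peptidase gene tpp1 43795 reads against 3 and the nucleoporin gene nup62 3761 reads against 2. The level of nup62 was 34.3 CPM in prespore-like cells, below the 202 to 420 CPM of third-cluster cells in replicates 1 and 2. Also higher were p80 (log2 9.53 ± 0.95), a gene of an endosomal protein, and manF (log2 8.72 ± 1.44).

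Higher in prestalk-like cells, with log2 fold changes ± SE of prespore-like over prestalk-like sums, were rsc12 (-7.33 ± 1.21), cbpK (-6.98 ± 0.70), psiA (-6.73 ± 0.93), hmgB (-6.50 ± 1.00), csbB (-5.50 ± 0.62), csbA (-5.01 ± 0.76), CYP521A1 (-4.77 ± 0.84), cryS (-4.28 ± 0.73), omt4 (-4.15 ± 0.48) and pks32 (-4.14 ± 0.66), a polyketide synthase gene. rsc12 had 62.4 ± 54.03 against 4324 ± 3965 CPM. Of the genes without a symbol, DDB_G0283733 (7.56 ± 0.72) was higher in prespore-like cells, as was DDB_G0292362 with 19198 reads against 2. DDB_G0285871 with 1185 reads against 0 was 203-fold higher against the floor. Its 13.7 CPM in prespore-like cells lay below the 127 to 511 CPM of third-cluster cells in replicates 1 and 2. DDB_G0280999 (-10.35 ± 1.78), DDB_G0268640 (-8.96 ± 0.94) and DDB_G0275155 (-6.26 ± 1.08) were higher in prestalk-like cells.

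All 155 genes had the same direction in 3 of 3 replicates. Here and in the comparisons below, a shared direction follows largely from the calling, which used the same sums. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of the 34 named genes passed in every fit that left out a replicate. By that test 0 genes passed without replicate 2 (892 at an unadjusted p under 0.05), 0 without replicate 3 (1745 unadjusted), 288 without replicate 1, and DESeq2 called 2390. With the 7 left-out cells added, the third cluster of replicate 3 reached 5 cells and entered the fit as another sum, and 1 gene passed. With these cells and the same 8 sums, chosen after seeing the data, 150 passed. With spike-in totals as library sizes 67 passed, 52 higher and 15 lower in prespore-like cells, so the balance of directions depends on scaling, and the median log2 difference of all genes was 1.04 in place of 0.76.

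Of 17 lists, 5 passed in this comparison. Other splits of the 6 prespore-like and prestalk-like sums passed 1 to 5 lists, so this count alone does not set the real classes apart. Proteasome genes were higher in prespore-like cells (median log2 difference 2.19, camera adjusted p = 4.92e-07, adjusted p = 0.249 with an estimated correlation). Of 39 members 1 passed alone, psmD13 at 147 ± 14.7 against 6.89 ± 2.99 CPM, and 14 passed adjusted over the list alone. The list of DIF synthesis, a signal that induces prestalk cells, was higher too (3 members, adjusted p = 0.0211, adjusted p = 0.370 with an estimated correlation). Of these 1 passed alone, the methyltransferase gene dmtA with 8821 reads against 1, and 2 passed adjusted over the list alone. Actin-binding and motor genes were lower in prespore-like cells (median -1.13, adjusted p = 8.88e-12, adjusted p = 0.370 with an estimated correlation). Of 34 members 3 passed, the myosin light chain genes mlcE at 482 ± 122 against 1653 ± 447 CPM and mlcR at 173 ± 46.8 against 716 ± 152 CPM and the cortexillin gene ctxB at 716 ± 219 against 2194 ± 672 CPM, and 16 passed adjusted over the list alone. The mixed list of aggregation and cAMP genes was lower (median -0.62, camera adjusted p = 0.00471, adjusted p = 0.303 with an estimated correlation). The 1 of 20 that passed alone, aprA (5.80 ± 1.01), was higher, and 3 passed adjusted over the list alone. For developmental transcription factors (adjusted p = 0.0211 for lower, adjusted p = 0.482 with an estimated correlation) 0 of 27 passed, also adjusted over the list alone, and the median was -0.26, the mean 0.01 and the median with spike-in totals 0.02, so the signs differ.

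The other 12 lists did not pass, at camera adjusted p of 0.0650 or above. They were the Tgr adhesion family, growth and lysosome, discoidin, cell cycle, ribosomal proteins, the proton pump, heat shock, histones, late spore and stalk genes, tip patterning, autophagy and expansins. In these lists p80, pcna and wacA passed alone. pcna, the DNA sliding clamp gene, had 3671 reads against 0, 437-fold higher in prespore-like cells against the floor. The spore gene wacA had 77.02 ± 36.7 against 0.117 ± 0.202 CPM. The list of sentinel cell genes had 2 tested members, too few for the list test.

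The third cluster differed from prespore-like cells in 855 of 11541 genes, 138 higher and 717 lower in the third cluster. The log2 fold changes ± SE below are of the third cluster (2 sums) over prespore-like cells (3 sums). The adhesion genes tgrM1 (-7.87 ± 0.47), tgrQ1 (-7.63 ± 0.72), tgrD1 (-7.06 ± 0.49) and tgrC1 (-6.23 ± 0.58) were lower, as was csaA, an adhesion gene of aggregating cells, at 177 ± 81.4 against 2071 ± 684 CPM (adjusted p = 0.00160). Also lower were patA (-8.72 ± 1.21), ponH (-8.01 ± 1.45), 5NT (-7.41 ± 0.84), gadA (-7.07 ± 0.88), rsmJ (-7.06 ± 0.94), tpp1 (-7.04 ± 1.13) and rapgapB (-6.95 ± 0.67). Higher were the ribosomal protein genes rps7 (5.17 ± 1.22), rpl12 (4.94 ± 0.74), rps20 (4.79 ± 0.81), rpl4 (4.25 ± 0.98) and rplP1 (4.24 ± 0.99), together with V4-7 (7.05 ± 1.05), the vacuolin gene vacB (5.07 ± 0.61), the superoxide dismutase gene sodC (4.93 ± 0.57), lmcB (4.81 ± 0.91) and exdl2A (4.15 ± 0.52). V4-7 had 1395 and 796 CPM in replicates 1 and 2 in third-cluster cells with few reads at the start of chromosome 1, and 0.288 and 18.2 CPM in the other 26, a division chosen after the values were seen. csaA had 545 and 389 CPM in the former and 65.04 and 24.6 CPM in the latter. Of the genes without a symbol, DDB_G0267282 (6.86 ± 1.13), DDB_G0290431 (6.29 ± 1.45) and DDB_G0267334 (5.98 ± 0.49) were higher, and DDB_G0276729 (-10.69 ± 0.72) and DDB_G0281917 (-9.54 ± 0.72) were lower. DDB_G0268250, with 0 reads against 556 (4.42 CPM in prespore-like cells), was 255-fold lower against the floor.

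All 855 genes had the same direction in replicates 1 and 2, and 28 of the 58 named genes passed in every fit that left out a replicate. Of the 58, 55 had their direction in both replicates in each of these 2 kinds of third-cluster cell, and V4-7, DDB_G0267282 and DDB_G0267334 did not. Between the 2 kinds, 12 of the 58 differed over 4-fold in both replicates (1 CPM added). The median log2 difference of all genes was 0.76, against -0.93 for the 2748 genes with at least 50 CPM, of which 682 passed as lower. With spike-in totals as library sizes it was 1.35 for all genes, and 29.03% of 589 calls were higher in place of 16.1%. The count was 382 without the 26 cells of the third cluster with many reads at the start of chromosome 1, and DDB_G0267282 and DDB_G0267334 then turned to -1.80 and -0.81. With only those 26 cells as the third cluster, the count was 1098. It was 348 without replicate 2, 481 without replicate 3 and 2597 with DESeq2.

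Of 17 lists, 9 passed against prespore-like cells. Ribosomal protein genes were higher in the third cluster (median 3.34, camera adjusted p = 8.44e-11, adjusted p = 0.498 with an estimated correlation), with 11 of 78 past the threshold and 57 adjusted over the list alone, rps23 at 583 ± 103 against 46.02 ± 38.5 CPM and rps3 at 1891 ± 186 against 583 ± 145 CPM among the 11. Heat shock genes were higher (adjusted p = 0.00724, adjusted p = 0.614 with an estimated correlation), with 5 of 25 and 14 adjusted over the list alone, hspD at 10564 ± 1872 against 2819 ± 398 CPM, hspG2 (2.43 ± 0.44), hspG3 (3.62 ± 0.69) and hspG4 (3.15 ± 0.66) among them. Proteasome genes were higher as a list (adjusted p = 0.0158, adjusted p = 0.255 with an estimated correlation), with 0 of 39 past the threshold, also adjusted over the list alone.

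Lower in the third cluster were Tgr genes, with 9 of 37 past the threshold and 9 adjusted over the list alone (median -2.91, adjusted p = 2.98e-07, adjusted p = 0.178 with an estimated correlation). Of 27 developmental transcription factors 14 were lower and 16 adjusted over the list alone (adjusted p = 3.82e-08, adjusted p = 0.178 with an estimated correlation), among them the GATA factor gene gtaI (-3.76 ± 0.38), CRTF (-3.46 ± 0.36), the MADS-box gene srfA (-6.75 ± 0.70) and the STAT gene dstC (-3.70 ± 0.40). Of 20 aggregation and cAMP genes 7 were lower and 11 adjusted over the list alone (camera adjusted p = 9.27e-05, adjusted p = 0.178 with an estimated correlation), among them the G protein gene gpaB (-3.53 ± 0.40), erkA (-3.98 ± 0.58) and the cAMP receptor gene carA-2 (-2.21 ± 0.32). Of 34 actin-binding and motor genes 9 were lower and 14 adjusted over the list alone (adjusted p = 0.000263, adjusted p = 0.498 with an estimated correlation), among them abpC (-4.75 ± 0.50), the myosin heavy chain gene mhcA (-2.89 ± 0.33), mlcE (-2.44 ± 0.32) and ctxA (-2.77 ± 0.39). The median of this list was -0.65 (-0.07 with spike-in totals), not below the -0.93 of genes with at least 50 CPM; camera compares it with all tested genes. Of 14 late spore and stalk genes 5 were lower and 6 adjusted over the list alone (adjusted p = 0.000356, adjusted p = 0.255 with an estimated correlation), among them the cellulose synthase gene dcsA (-5.42 ± 0.34), tpsA (-3.35 ± 0.43) and ugpB (-2.90 ± 0.46). Of 17 tip patterning genes 4 were lower and 5 adjusted over the list alone (adjusted p = 0.00724, adjusted p = 0.255 with an estimated correlation): dhkA (-4.73 ± 0.60), carC (-5.86 ± 0.92), amtC (-2.63 ± 0.51) and amtB (-2.27 ± 0.51). Its median of -0.97 (-0.37 with spike-in totals) and its 4 of 17 stand beside -0.93 and 682 of 2748 for genes with at least 50 CPM, a difference not tested. In the 8 lists that did not pass, at adjusted p of 0.134 or above, the cathepsin-like protease genes cprB (-4.48 ± 0.31) and cprA (-3.49 ± 0.57), the cyclin gene cycD (-6.19 ± 1.19) and the expansin-like genes expl8 (-6.53 ± 0.49) and expl6 (-5.74 ± 0.70) were lower. The lysozyme gene alyD-2 (4.68 ± 1.08), of the sentinel cell genes, was higher.

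The third cluster differed from prestalk-like cells in 1746 of 11541 genes, 705 higher and 1041 lower in the third cluster. The values below are of the third cluster (2 sums) over prestalk-like cells (3 sums). The polyketide synthase genes pks3 (-8.68 ± 1.64), pks32 (-7.95 ± 0.95) and pks30 (-7.49 ± 0.88) were lower, as were patA (-8.53 ± 1.20), rsc12 (-8.30 ± 1.50), gpt5 (-8.20 ± 1.18), csbA (-8.16 ± 1.06), rapgapB (-8.13 ± 0.70), 5NT (-8.03 ± 0.85) and srfA (-7.71 ± 0.73). The mRNA export gene rae1 was higher at 1156 ± 137 against 4.28 ± 6.67 CPM, as were the splicing factor genes prpf31 at 210.0 ± 32.1 against 0.679 ± 1.18 CPM and eftud2 at 171 ± 110.5 against 0.936 ± 1.62 CPM, ubqK (7.98 ± 1.80), 29C (8.06 ± 1.68) and V4-7 (11.13 ± 1.22). The helicase gene dhx35 had 38820 reads against 0 in the prestalk-like sums, 3315-fold higher against the floor. aqpA had 1115 reads against 0, 94.5-fold higher against the floor. nup62 had 45827 reads against 2 and catB 925 reads against 1. Levels of aqpA and catB were low here, and prespore-like cells, with 185 and 254 CPM, raised their means over all sums. In replicates 1 and 2, aqpA had 3.86 and 8.40 CPM in third-cluster cells with many reads at the start of chromosome 1. The others had 3.92 and 11.3 CPM. catB had 11.9 and 9.43 CPM in the former and 0 and 0.259 CPM in the latter. Of the genes without a symbol, DDB_G0285871 with 50269 reads against 0 was 4363-fold higher against the floor, DDB_G0292362 had 39346 reads against 2 and DDB_G0279503 17164 reads against 3. DDB_G0280999 (-12.53 ± 2.27) and DDB_G0275155 (-11.95 ± 1.67) were lower, and DDB_G0268250, with 0 reads against 6755, was 8286-fold lower against the floor.

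All 1746 genes had the same direction in replicates 1 and 2, and 39 of the 76 named genes passed in every fit that left out a replicate. Of the 76, 72 had their direction in both replicates in each of the 2 kinds of third-cluster cell, and V4-7, catB, smc4 and dmtA did not. Between the 2 kinds, 13 of the 76 differed over 4-fold in both replicates (1 CPM added). The median log2 difference was 1.69 for all genes and -1.09 for the 2748 genes with at least 50 CPM, of which 936 passed as lower. With spike-in totals it was 2.57 for all genes, and 61.2% of 1611 calls were higher in place of 40.4%. With only the third-cluster cells that had many reads at the start of chromosome 1, 1923 genes passed. The count was 974 without the cells with many reads at the start of chromosome 1, 992 without replicate 1, 586 without replicate 2 and 5338 with DESeq2.

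Of 17 lists, 9 passed against prestalk-like cells. Higher in the third cluster were 47 of 78 ribosomal protein genes and 68 adjusted over the list alone (adjusted p = 1.15e-08, adjusted p = 0.587 with an estimated correlation), among them rps23 (4.41 ± 0.53), rps3 (2.87 ± 0.37), rps18 (5.72 ± 0.78) and rpl31 (5.68 ± 0.79). Of 39 proteasome genes 24 were higher and 35 adjusted over the list alone (adjusted p = 3.06e-06, adjusted p = 0.135 with an estimated correlation), among them psmC3 (4.15 ± 0.52), psmD13 (4.55 ± 0.62), psmB3 (5.22 ± 0.91) and psmD7 (3.59 ± 0.64). Of 25 heat shock genes 11 were higher and 15 adjusted over the list alone (adjusted p = 0.0173, adjusted p = 0.633 with an estimated correlation), among them hspG4 (5.50 ± 0.74), hspG3 (4.78 ± 0.72), hspM (3.56 ± 0.58) and hspG9 (2.56 ± 0.50).

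Lower in the third cluster were 16 of 34 actin-binding and motor genes and 20 adjusted over the list alone (adjusted p = 3.74e-11, adjusted p = 0.225 with an estimated correlation), among them mlcE (-4.21 ± 0.35), mhcA at 573 ± 87.5 against 9899 ± 2021 CPM, abpC (-5.77 ± 0.53) and ctxB (-4.00 ± 0.38). mhcA had 1488 and 1654 CPM in third-cluster cells of replicates 1 and 2 with few reads at the start of chromosome 1. It had 83.9 and 56.8 CPM in the other 26. Of 27 transcription factors 15 were lower and 17 adjusted over the list alone (adjusted p = 1.71e-08, adjusted p = 0.135 with an estimated correlation), among them gtaI (-4.73 ± 0.40), CRTF (-4.07 ± 0.37) and dstC (-3.84 ± 0.40). Of 20 aggregation and cAMP genes 10 were lower, 1 was higher and 12 passed adjusted over the list alone (camera adjusted p = 8.64e-07, adjusted p = 0.135 with an estimated correlation), csaA at 177 ± 81.4 against 4906 ± 989.5 CPM, carA-2 (-3.16 ± 0.34), gpaB (-3.56 ± 0.40) and erkA (-4.56 ± 0.59) among the lower ones. Of 37 Tgr genes 9 were lower, 1 was higher and 11 passed adjusted over the list alone (adjusted p = 3.98e-06, adjusted p = 0.152 with an estimated correlation), tgrM1 (-6.76 ± 0.44), tgrD1 (-6.65 ± 0.48), tgrC1 (-6.22 ± 0.57) and tgrR2 (-4.75 ± 0.47) among the lower ones. Of 14 late genes 8 were lower and 11 adjusted over the list alone (adjusted p = 0.000506, adjusted p = 0.225 with an estimated correlation), among them dcsA (-6.51 ± 0.36), tpsA (-3.16 ± 0.42) and ugpB (-2.26 ± 0.45). Of 17 tip patterning genes 5 were lower and 5 adjusted over the list alone (adjusted p = 0.00120, adjusted p = 0.152 with an estimated correlation), among them dhkA (-5.07 ± 0.60), amtB (-3.25 ± 0.53), zakA (-3.64 ± 0.74) and amtC (-2.14 ± 0.49). The median of this list was -1.43, against -1.09 for genes with at least 50 CPM.

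In the 8 lists that did not pass against prestalk-like cells, at adjusted p of 0.326 or above, members went both ways. Higher were p80 (7.51 ± 0.92) and cprE (7.21 ± 1.43) of growth and lysosome, the proton pump genes vatE (3.10 ± 0.52), vatB (3.94 ± 0.70) and vatC (2.32 ± 0.64) and the histone gene H2Bv1 (6.26 ± 0.86). pcna had 10529 reads against 0 and smc4 2453 reads against 0, 904-fold and 211-fold higher against the floor. dmtA had 418 reads against 1. Lower were cprB (-5.31 ± 0.33), cprA (-4.31 ± 0.58), the cell cycle kinase gene cdk1 (-4.12 ± 0.81), cycD at 1.31 ± 1.28 against 55.9 ± 32.7 CPM, expl8 (-7.03 ± 0.50) and expl6 (-6.13 ± 0.71). The lysozyme gene alyD-2 (8.44 ± 1.40) was higher. By fry, which asks whether a list moves 1 way on balance, 3, 8 and 12 lists passed in the comparisons in the order given here, and by camera with an estimated correlation 0 passed in each.

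Without classes, 37 of 3257 genes stood among the most variable 5% in every replicate, where independent rankings would give 0.407. The 10 named, outside the markers, were psiA, V4-7, rsc12, celB, cprG, abhd, pks3, abpF, CYP519E1 and cupI. The ratio of the variability of psiA to the running median at the same mean had a median of 20.2 over replicates, that of V4-7 17.7, rsc12 16.1, celB 7.91 and cprG 7.60. The prestalk markers ecmB and ecmA had 11.3 and 10.2. psiA had a read in 58.6%, 31.8% and 34.9% of the cells of replicates 1, 2 and 3, and rsc12 in 55.2%, 70.5% and 20.9%. Of the markers, 0 of 9 ranked prespore genes and 2 of 11 ranked prestalk genes were among the 37. The count was 16 of 1020 genes with a mean of at least 100 CPM, where independent rankings would give 0.128.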

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

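The tests of depth, of culture or chip, of reads on overlapping features, of reads lost to genes at the start of chromosome 1 and of 2 cells in 1 chamber were chosen only after the result was seen. For the test of genomic DNA, the cells compared were divided by a bound that was also set after the values were seen. In 1 kept cell of the third cluster, reads that lay on more than 1 feature reached 21.3% of the gene reads, and in 1 kept cell reads on no feature reached 6.55%; both lie outside the counts compared above. Among the 7 cells the authors left out, 1 had 4259 genes detected, although 78.2% of its reads were spike-ins.

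Part of the third cluster took many reads from genes at the start of chromosome 1 (67 counted genes among the first 80 of the assembly dicty_2.7). 26 of its 46 cells had between 2.12% and 22.5% of their gene reads there and 20 had at most 0.782%; these are the 26 and 20 cells that 200 variable genes separated, and 2 cells of other classes exceeded 2%, a bound set after the values were seen. The share went with that of reads on more than 1 feature. The Spearman rho across cells, which are not replicates, was 0.891 and 0.931 in replicates 1 and 2. It was 0.90 and 0.934 within the 26 cells, and 0.321 and -0.310 within the others. Reads on overlapping features may thus have set the levels of single genes. Reads shared between near-identical copies are not what this share counts, so the rho does not bear on them. The median share of reads on no feature was 1.84 times higher in the 26 cells, which goes with genomic DNA. Unspliced or nuclear RNA would raise it too and was not tested. Loss of reads to these genes alone is argued against, since their largest share in 1 cell lowers any other gene by 0.37 on the log2 scale, while 268 other genes separated these cells by more than 2. What separates the 2 kinds of cell stays open, and no biological explanation was tested.

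The share of prespore-like cells ranged over 59.5 percentage points between replicates. Sequencing depth alone is argued against, since the range was 59.5 after thinning to 700000 reads. Thinning evens out reads and not the RNA captured per cell, so it does not bear on the latter. After thinning, the median number of genes detected was 6374, 5314 and 4126 in replicates 1, 2 and 3. Culture, chip, library set and developmental timing cannot be told apart (range 59.5), since the labels record none of them within a replicate, and no biological explanation was tested. Replicate 3, with 76.7% against 17.2% and 31.8%, also stands apart in its sample titles, which follow 1 naming scheme in replicates 1 and 2 and another in replicate 3.

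Third-cluster cells had more genes detected than prespore-like cells, by 1901 on average in replicates 1 and 2, but in replicate 2 the difference lay in the 17 cells with many reads at the start of chromosome 1, with a median of 8007 against 5790.5 in prespore-like cells and 5510.5 in the 8 others. After thinning the difference was 2032 (2182 and 1882.5 in the 2 replicates; in replicate 2 the 17 cells had 7050, prespore-like cells 4866.5 and the 8 others 4842), which argues against depth. Chambers holding a prespore-like and a prestalk-like cell would hold RNA of both types. In the third cluster, 72 genes outside the markers that were higher in prestalk-like cells had a median of 3.38% of their prestalk-like level (quartiles 1.37% and 10.4%). The median was 2.42% and 4.13% in cells with many and few reads at the start of chromosome 1. The 48 genes higher in prespore-like cells had 9.70% of their prespore-like level (2.35% and 100.9%). Third-cluster cells scored low on both panels, which made the classes, so mixed chambers would likely have been placed in another class beforehand. The test thus adds little for the third cluster. Mixed chambers in other classes were not examined, and 35 prespore-like cells had both scores above 0. Pairs of third-cluster cells stay open, and no biological explanation was tested. Gene reads per spike-in read, not tested, were 3.21 in prespore-like cells of replicate 2, 4.57 in the 17 cells and 2.50 in the 8 others, and 2.21, 3.08 and 3.82 in the same order in replicate 1.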

How the results depend on the processing

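Only the alternatives that split the third cluster by its chromosome 1 start share, the thinning of shares and the 7 added cells with the same 8 sums were chosen after seeing the data. The replicate block is part of the fits; without the replicate block 262 genes (59.2% higher) passed for prespore-like against prestalk-like cells and 2974 for the third cluster against prestalk-like cells (56.4% higher); it was 1122 against prespore-like cells, and 5, 8 and 8 lists passed. In the order prespore-like against prestalk-like, the third cluster against prespore-like and the third cluster against prestalk-like, DESeq2 called 2390, 2597 and 5338 genes (71.9%, 52.9% and 70.2% higher, against 49.03%, 16.1% and 40.4%), marker centring 42, 403 and 1123 (50%, 0.248% and 27.6% higher), 4 clusters 10, 0 and 221, and tertiles of the score difference 0, 0 and 0 (758, 240 and 681 unadjusted). For 4 clusters the 0 stands beside 510 unadjusted, and the prespore-like side was 1 sum of 6 cells of replicate 3, with the other 46 prespore-like cells counted with the third cluster; tertiles put 23 of the 46 third-cluster cells in the middle. Both thus compare other cells, and their counts and signs do not retest the classes. Spike-in totals gave 67, 589 and 1611 (77.6%, 29.03% and 61.2% higher). Adding the 7 left-out cells gave 1 in the first and 426 in the second, but also brought in a sum of 5 cells for the third cluster of replicate 3; with the same 8 sums it gave 150, 864 and 1745. In the second, log2(CPM+1) gave 552. Leaving out cells of the third cluster with a high chromosome 1 start share gave 382 against prespore-like and 974 against prestalk-like cells. Keeping only those cells in the third cluster gave 1098 and 1923. Leaving out each replicate gave 0 to 288, 348 to 674 and 586 to 1321; where 1 sum of the third cluster is left, it is assumed to vary like the others. The cause was not tested. With an estimated correlation 0, 0 and 0 lists passed, and with fry 3 in the first, while leaving out replicates gave 3 to 7 in the first. With 2 clusters both scores were highest in 1 cluster, so no value exists. The prespore-like share was 4.65% with 4 clusters, for those 6 cells. The between-panel rho ranged from -0.0550 to 0.127 without single replicates, reversed at -0.00646 and -0.0550. Variable genes numbered 16 at 100 CPM and 51 to 95 without single replicates, where 2 rankings are intersected in place of 3 and independent ones would give 8.39 to 11.1 in place of 0.407. The agreement was 0.550 with 200 genes and 0.521 with log2(CPM+1). Of the values of named genes under alternatives, 168 came from clusters on 500 other genes, whose classes equalled the main ones, so these could not differ. With them included, 2237 values kept direction and side of the threshold, 725 lost the threshold and 27 turned sign. With tertiles of the score difference these were, for prespore-like against prestalk-like, nup62 -0.48, DDB_G0285871 -0.41 and DDB_G0283733 -0.90; against prespore-like, hspG4 -0.11 and alyD-2 -0.16; against prestalk-like, dhx35 -0.33, V4-7 -0.64, 29C -0.55, DDB_G0285871 -0.017, tgrM1 0.18, cprE -1.78, pcna -0.078, rps23 -0.75, rps18 -0.24, rpl31 -1.80, vatB -0.35, vatC -0.64 and alyD-2 -1.15. With 4 clusters, where 1 sum of those 6 cells stands for prespore-like, they were rsmJ 0.038, rapgapB 0.11, DDB_G0268250 1.19, abpC 0.51, mlcE 0.35, ctxA 0.41 and dhkA 0.082. Without the cells with a high start share, DDB_G0267282 was -1.80 and DDB_G0267334 -0.81. The spread between sums limits the calls, since 24%, 32% and 26% of 16-fold changes were recovered in simulation. The changed genes were drawn from low and high levels alike, and recovery of abundant genes alone was not simulated.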

Other observations

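The comparison of 2 kinds of cell in the third cluster and the test of runs were chosen only after the result was seen. Within the third cluster, the 18 cells of replicates 1 and 2 with few reads at the start of chromosome 1 had higher levels of mhcA, V4-7, cfaD and dstC than the other 26. The myosin heavy chain gene mhcA had 1488 and 1654 CPM in these cells in replicates 1 and 2, against 83.9 and 56.8 CPM in the others. V4-7 had 1395 and 796 CPM against 0.288 and 18.2 CPM, cfaD 2861 and 3129 against 103 and 83.6 CPM, and the STAT gene dstC 542 and 777 against 30.9 and 24.4 CPM. In the 26 cells, higher levels were found for rae1, at 2051 and 2181 CPM against 484 and 92.4 CPM, xrn2 at 1578 and 1251 against 663 and 75.0 CPM, and prpf31 at 512 and 324 against 82.3 and 33.8 CPM. DDB_G0267180, at the start of chromosome 1, had 75482 and 70454 CPM against 457 and 153 CPM. The genes were the extremes of the log2 ratio, so their differences are not tested, and counts of near-identical copies are uncertain.

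The authors left out cells that lacked a contiguous part of the transcriptome, per the series' design text, so short runs in the kept cells follow in part from that choice. Along the gene order of dicty_2.7, over 2864 genes with at least 50 CPM, the longest run of genes without a read was 8 in the third cluster, 10 in prespore-like and 11 in prestalk-like cells. In 8 of the 116 kept cells, 3 of them in the third cluster, 3 prespore-like and 2 prestalk-like, the run was longer than in each of 20 shuffled orders of the same cell, beside a mean of up to 5.52 cells by chance, a difference not tested.

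For prespore-like against prestalk-like cells, 10 splits of the 6 sums are too few for a share under 0.05. The real split gave 155 genes and the highest other split 0, and 1 split, the real one, gave as many. The real split was made from the same cells' expression, so it was bound to part more genes than splits that mix the classes. Some other splits also put both sums of a replicate on the same side. The gene counts thus do not bear on chance. For lists the real split gave 5, the highest other split 5, and 2 splits gave as many.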
